A study of Homo sapiens with 35 samples.

How the data were processed

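RNA of 14 CCSK, 15 Wilms tumours and 3 fetal kidneys was measured on 35 Affymetrix 3 prime arrays with 22283 probe sets. The deposited values are intensities, scaled by the authors so that the mean over the middle of the probe sets, after trimming 2% at each end, was 2500.6 to 2500.8 on every array. The values are linear, the distributions differ between arrays, and the software that summarised the probes is not given in the sources used here. Samples were grouped by their labels. Wilms tumours 1 to 3 had 2 arrays each, whose labels end in R1 and R2. What R stands for is not stated, and their log2 values were averaged, giving 32 tumours and kidneys. The 2 arrays of these tumours correlated at 0.922, 0.894 and 0.917, and tumour 2 had a higher correlation, 0.900, with an array of another tumour. The labels give no batch or scan date, so none was modelled. The number of arrays limits the precision, most of all that of the 3 fetal kidneys.

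The values were used as log2(intensity + 16) with no further normalization. A probe set was kept if it exceeded the 40th percentile of its own sample in at least 3 of the 32 samples, which kept 17105. Gene symbols came from the probe annotation, and gene names were checked by gene ID against a reference table of assembly GRCh38.p14, used for names alone, and older symbols in the lists were replaced through its synonyms. Of the probe sets, 19071 had 1 gene symbol, 1043 had several and 2169 were not listed. The kept probe set with the highest mean stood for each of 10023 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend) in 1 fit of all 3 groups, with 29 residual degrees of freedom. The p-values were two-sided and were adjusted by the Benjamini-Hochberg method within each comparison. The threshold was an adjusted p of 0.05. A second count also required a 2-fold difference.

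A total of 23 gene lists were tested with camera (limma) with a preset correlation of 0.01 between genes, adjusted over 69 tests, and again with an estimated correlation. The lists were neural, neural crest and Schwann cell, hedgehog pathway, PI3K and AKT pathway, receptor tyrosine kinases, BCOR and YWHAE sarcoma, nephron progenitor and blastema, early nephron, Wnt response, podocyte, proximal tubule, distal nephron and collecting duct, epithelial, skeletal muscle, smooth muscle and pericyte, mesenchyme and matrix, proliferation, endothelial, leukocyte, erythroid, immediate early and heat shock, hypoxia, and imprinted. With the preset correlation 9, 11 and 13 lists passed in CCSK against Wilms tumour, CCSK against fetal kidney and Wilms tumour against fetal kidney, and 3, 7 and 6 of these also with the estimated correlation. The latter had adjusted p up to 0.0471 with it, mostly far larger than with the preset one. The text prints the adjusted p with the estimated correlation mainly for lists that then did not pass. Some lists have few measured members, and some genes stand in more than 1 list. The median, the mean and the direction of the test differed in sign for 9 of the 69 tests, none of which passed. These were the proximal tubule and leukocyte lists in CCSK against Wilms tumour, the early nephron, immediate early and heat shock, and imprinted lists in CCSK against fetal kidney, and the neural, PI3K and AKT, skeletal muscle and hypoxia lists in Wilms tumour against fetal kidney.

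The grouping, lists, tests, alternatives and the rule for naming genes were set before the data were examined. Named genes were, for each comparison, the 8 passed genes with the largest positive and the 8 with the largest negative difference in which at least 90% of the higher group lay above the median of the lower group. Each list added up to 4 passed members, those with the 2 largest and 2 smallest differences, or the member with the smallest p where none passed. Genes always named included NGFR, CCND1, BCOR, EGFR, PTCH1, GLI1, GLI2, PDGFRA, TCF21, IGF2, WT1, SIX2, PAX2, PAX8, CITED1, SALL1, CDH1 and H19, of which IGF2 and H19 had no kept probe set with 1 symbol. XIST, Y-linked genes, immunoglobulin genes and haemoglobin genes were left out of the first part of the rule. The rule takes 104, 102 and 91 genes in the 3 comparisons, and the text prints a part of them.

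No detection calls were used. A background level was set, by a rule chosen after seeing the data, as the 95th percentile of 27 Bacillus control probe sets in each sample, with a mean of 8.97 on the log2 scale or an intensity of 485.2. Where samples of the dimmer group lay at or below it, the fold was computed against that level and is given as "at least". A difference printed for such a gene moves with the pseudocount and is no bound. RNA quality was log2 of the 3 prime over 5 prime signal of the GAPDH and beta-actin control probe sets, compared by permutation (scipy 1.17.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3). Figures were drawn with matplotlib 3.10.9, and tables were read with the data.table package, version 1.17.8.

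The steps were tested on simulated data of 10023 genes, in which 100 genes each were shifted 2-fold and 4-fold. They recovered 83% and 96% for CCSK against Wilms tumour, 42% and 80% for CCSK against fetal kidney, and 46% and 88% for Wilms tumour against fetal kidney, with 12, 8 and 8 false calls among 191, 130 and 142. In each comparison 0 of 20 unshifted lists and 20 of 20 shifted lists were called. The simulated genes were drawn independently of each other, whereas the estimated correlation of the proliferation list was 0.598. The simulation therefore does not give the error rate for lists whose genes correlate. Alternatives tried were other pseudocounts, quantile normalization, median centring, no filter and a stricter filter, other probe set choices, other variance models, array weights, single arrays per tumour, all 35 arrays with the tumour as a random block, the replicate number as a block, the RNA quality measure as a covariate, the 2 groups of a comparison alone, and leaving out each sample. After seeing the data, a larger pseudocount and a fit without Wilms tumours 1 to 3 were added. Probe sets with several symbols or none were left out of the gene tests.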

Results

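The arrays measured RNA from 14 clear cell sarcomas of the kidney (CCSK), 15 Wilms tumours and 3 fetal kidneys. CCSK is a childhood kidney sarcoma, and Wilms tumour is an embryonal kidney tumour that resembles the developing nephron. There were 35 arrays, since Wilms tumours 1, 2 and 3 each had 2 arrays, which were averaged. Levels are log2 of the deposited intensity plus 16, given as the mean ± SD, and each difference is given with its standard error (SE). The median intensity per array ran from 948.4 to 1355.6. The number of arrays, not a count depth, limits the precision, and the 3 fetal kidneys limit it most. The p-values measure only the spread between these samples. The labels number the tumours and kidneys but do not say whether they came from separate patients. The first principal component of the 10023 genes carried 35.6% of the variance, with CCSK scores from 35.7 to 61.9 and all scores of the other samples below 0. The second carried 7.69%, and its scores were 43.3 to 69.6 in the fetal kidneys and at most 16.9 in the tumours.

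**Figure D1:**
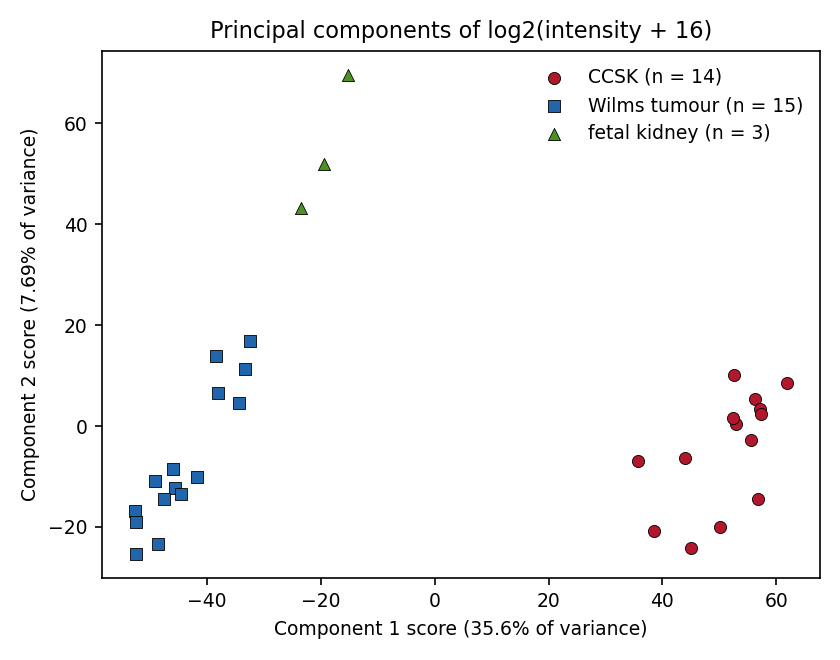
Scores of the 14 CCSK, 15 Wilms tumours and 3 fetal kidneys on the first 2 principal components of the log2 levels, with the share of the variance on each axis; each point is a tumour or kidney. The CCSK samples lie at 35.7 or above on component 1, and the fetal kidneys at 43.3 or above on component 2.

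The comparison of CCSK with Wilms tumour asks which genes set apart these kidney tumours. CCSK lacked the level of WT1, a transcription factor gene of the developing kidney, that Wilms tumours had: 6.07 ± 0.40 (SD, n = 14), at or below the background level in 14 of 14 samples, against 14.60 ± 0.45 (SD, n = 15), at least 54.8-fold lower. LHX2, a LIM homeobox transcription factor gene, was at least 29.5-fold higher in CCSK, at 13.96 ± 0.43 against 6.96 ± 1.18. The same held for MNX1, a motor neuron homeobox gene (at least 14.7-fold), GAD1, which encodes the enzyme that makes GABA (at least 21.8-fold), NPTX1, a neuronal pentraxin gene (at least 38.5-fold), and ALDH1A3, a retinoic acid synthesis gene (at least 32.1-fold). EYA1, a kidney progenitor gene, was at least 38.1-fold lower, MEOX1, a homeobox gene, at least 28.5-fold lower, and KRT19, an epithelial keratin gene, at least 4.22-fold lower. For each of these 9 genes, named for the size of their difference, every CCSK sample lay beyond every Wilms tumour. Among all 10023 genes this held for 265 higher and 185 lower in CCSK, where chance gives 2.58e-06% of genes.

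The nephron progenitor and blastema list held 17 measured members, of which 12 were lower in CCSK, 2 higher and 3 not passed; 12 lower and 2 higher when adjusted over the list alone (list adjusted p = 1.53e-08). SIX2, which keeps nephron progenitors in their undifferentiated state, differed by -3.12 (SE 0.25, adjusted p = 1.69e-12) and SALL1 by -1.65 (SE 0.17). PAX2 was at least 17.6-fold lower, while CITED1 differed by -0.27 (SE 0.19, adjusted p = 0.265). PAX8, from the early nephron list, differed by -1.61 (SE 0.24, adjusted p = 1.06e-06). That list nevertheless went the other way as a whole, with 7 of 11 members higher, 1 lower and 3 not passed, 8 and 1 when adjusted over the list alone (list adjusted p = 0.00474; adjusted p = 0.102 with an estimated correlation). Its higher members included WNT4 (at least 2.02-fold). Of 19 epithelial genes 12 were lower and 7 not passed, 14 lower and 1 higher when adjusted over the list alone; the list passed (adjusted p = 1.03e-05), and gave adjusted p = 0.0866 with an estimated correlation. EPCAM, an epithelial adhesion gene, was at least 15.1-fold lower. CDH1, the E-cadherin gene, was at least 1.18-fold lower, being at or below the background level in 14 of 14 CCSK and 7 of 15 Wilms tumours. TCF21, a gene of kidney mesenchyme and podocytes, was at least 7.17-fold lower.

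Hedgehog pathway genes were higher in CCSK as a set: 6 of 12 measured members higher, 1 lower and 5 not passed, with the same counts when adjusted over the list alone (list adjusted p = 8.74e-05). PTCH1, the hedgehog receptor and itself a target of the pathway, was 14.5-fold higher (difference 3.86, SE 0.14, adjusted p = 2.16e-22), and FOXF1, a forkhead gene, at least 22.3-fold higher. The transcription factor genes GLI1 and GLI2 were at least 10.3-fold and 3.43-fold higher, and GAS1, a hedgehog co-receptor gene, differed by -1.92 (SE 0.20). Of 24 neural genes 8 were higher, 4 lower and 12 not passed, with the same counts when adjusted over the list alone (list adjusted p = 0.0146; adjusted p = 0.0886 with an estimated correlation). The neurofilament gene NEFL was at least 49.9-fold higher and NEFM at least 13.2-fold, NGFR, the low-affinity nerve growth factor receptor gene, at least 5.25-fold, whereas NES, encoding nestin, was at least 5.36-fold lower and ENO2, a neuronal enolase gene, at least 3.07-fold. The PI3K and AKT pathway list did not pass (8 of 23 members higher, 5 lower and 10 not passed, the same adjusted over the list alone; list adjusted p = 0.0515). IRS2, an insulin receptor substrate gene, differed by 1.78 (SE 0.14). INPP4B, an inositol phosphatase gene, was at least 1.63-fold higher, with 14 of 15 Wilms tumours at or below the background level. PIK3CD, a PI3K catalytic subunit gene, was at least 2.33-fold lower, and TSC2 differed by -1.55 (SE 0.18), or by -0.19 (adjusted p = 0.540) where only probe sets without a cross-hybridisation suffix were used. The neural, hedgehog and PI3K and AKT lists are themes the study is known to report on these samples, so their counts are not independent evidence of direction.

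Of 14 genes of the BCOR and YWHAE sarcoma list 9 were higher, 2 lower and 3 not passed, 10 and 2 when adjusted over the list alone (list adjusted p = 9.34e-05). BCOR, a transcriptional corepressor gene, was 4.36-fold higher (difference 2.12, SE 0.15), BCL6, which encodes its partner, was 13.65 ± 0.46 (SD, n = 14) against 10.02 ± 1.34 (SD, n = 15), and CCND1, the cyclin D1 gene, was at least 10.3-fold higher, while PCGF1 differed by -0.63 (SE 0.10). Of 21 receptor tyrosine kinase genes 10 were higher, 2 lower and 9 not passed, with the same counts when adjusted over the list alone (list adjusted p = 0.00352; adjusted p = 0.102 with an estimated correlation). PDGFRA was at least 26.1-fold higher, FGFR3 at least 15.96-fold higher, and ERBB2 at least 4.48-fold lower. EGFR was at least 9.13-fold higher on its brightest probe set, and differed by -0.22 where only probe sets without a cross-hybridisation suffix were used. Of 25 mesenchyme and matrix genes 15 were higher, 4 lower and 6 not passed, unchanged when adjusted over the list alone (list adjusted p = 0.000339; adjusted p = 0.226 with an estimated correlation). TWIST1, a mesenchymal transcription factor gene, was at least 7.41-fold higher and POSTN, the periostin gene, at least 12.4-fold, but TNC, the tenascin C gene, was at least 10.8-fold lower. Of 28 proliferation genes 25 were lower, none higher and 3 not passed, 26 lower when adjusted over the list alone (list adjusted p = 1.71e-06; adjusted p = 0.323 with an estimated correlation). Among them MCM5, a replication helicase gene, differed by -2.07 (SE 0.25) and CENPF, a kinetochore gene, by -1.47 (SE 0.25).

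The other 13 lists did not pass against Wilms tumour. Markers of other cells and of tissue state moved as follows, as members higher and lower of those measured: endothelial 8 and 3 of 17, leukocyte 1 and 0 of 21, smooth muscle and pericyte 0 and 5 of 12, skeletal muscle 0 and 3 of 10, erythroid 0 and 2 of 7, immediate early and heat shock 7 and 4 of 19, and hypoxia 6 and 5 of 16. The kidney and developmental lists gave 4 and 5 of 13 podocyte genes, 1 and 2 of 15 proximal tubule genes, 4 and 1 of 17 distal nephron and collecting duct genes, 4 and 2 of 10 neural crest and Schwann cell genes, 7 and 5 of 15 Wnt response genes and 6 and 7 of 16 imprinted genes. In all, 1787 genes were higher and 2701 lower in CCSK, and 844 and 817 of these at least 2-fold. The RNA quality measure, log2 of the 3 prime over 5 prime control signal, was 1.43 ± 0.518 (SD, n = 14) in CCSK and 1.30 ± 0.521 (SD, n = 15) in Wilms tumour (two-sided permutation test, 100000 resamples, p = 0.525, adjusted p = 0.525 over 3 comparisons).

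**Figure D2:**
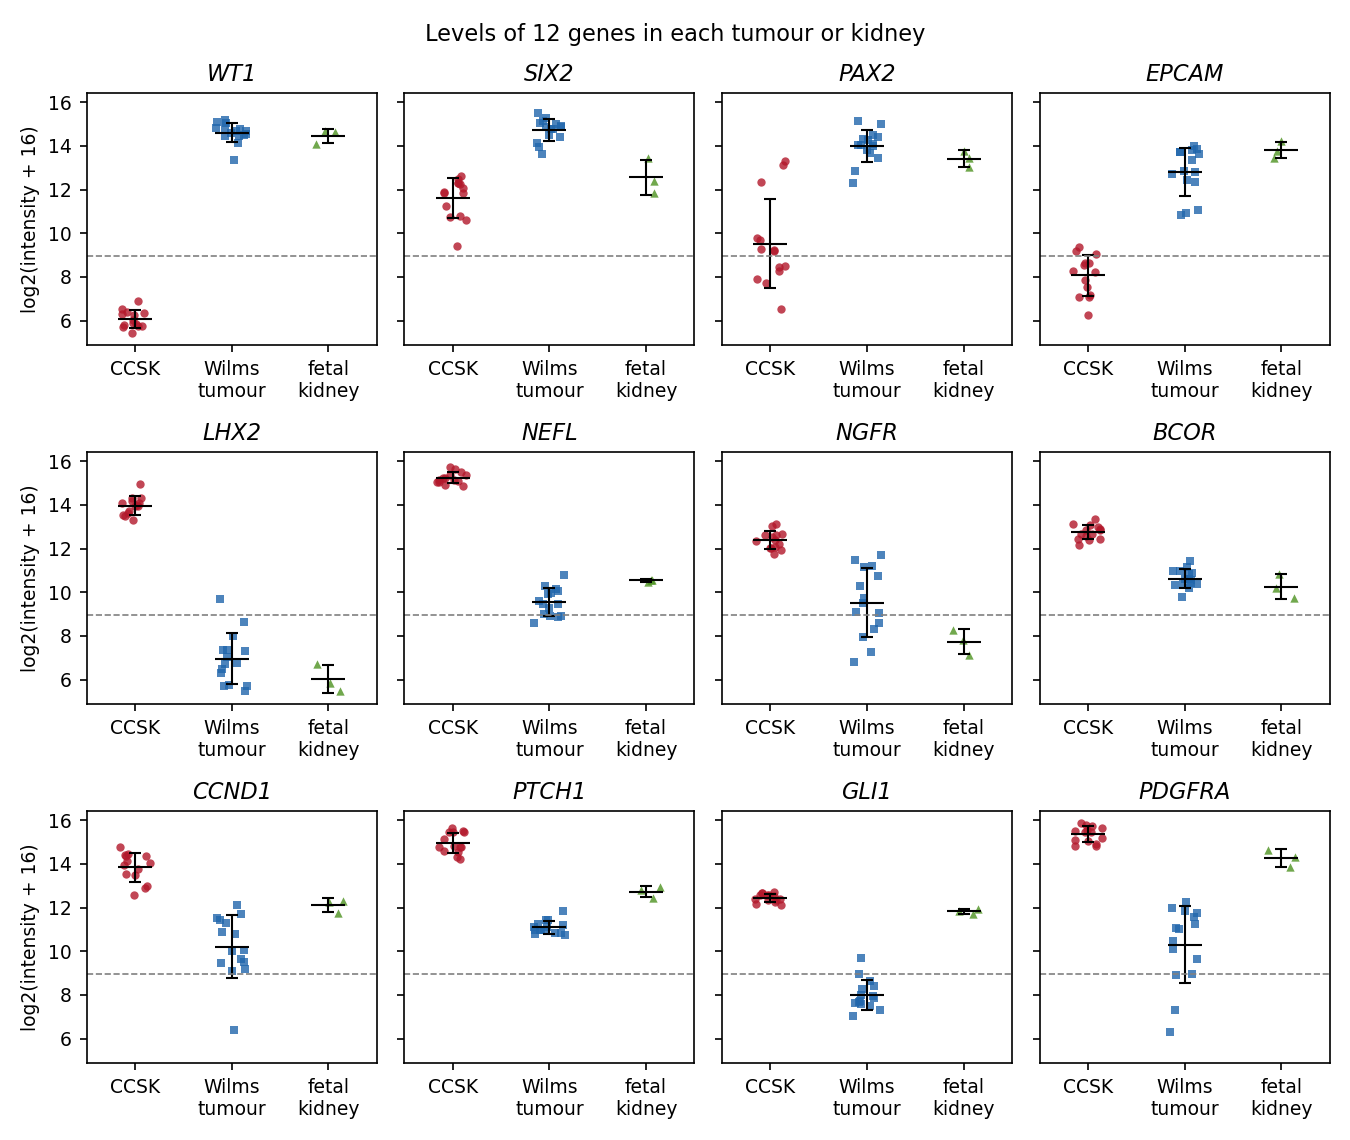
Log2(intensity + 16) of 12 genes in each of 14 CCSK, 15 Wilms tumours and 3 fetal kidneys; points are tumours or kidneys, the cross bar is the mean, the error bar 1 SD, and the dashed line the mean background level of 8.97. WT1 and EPCAM lie near or below the background level in CCSK, while GLI1 and PDGFRA are lowest in Wilms tumours.

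The comparison of CCSK with fetal kidney asks how the sarcoma differs from normal developing kidney. LHX2 was at least 26.4-fold higher in CCSK, at 13.96 ± 0.43 (SD, n = 14) against 6.03 ± 0.63 (SD, n = 3), and GAD1 at least 21.5-fold higher. ECEL1, a neuronal endopeptidase gene, was at least 44.3-fold higher, INHBB, an activin subunit gene, at least 15.5-fold, and EN2, a homeobox gene of the hindbrain, at least 12.2-fold. WT1 was at least 49.7-fold lower, KRT19 at least 9.51-fold and TCF21 at least 21.4-fold, and CDH1 was 6.31 ± 0.73 (SD, n = 14), at or below the background level in 14 of 14 samples, against 13.08 ± 0.24 (SD, n = 3). EMX2, a homeobox gene of the urogenital tract, was at least 24.7-fold lower. In these 10 genes, named for the size of their difference, no CCSK sample overlapped a fetal kidney. Among all 10023 genes this held for 452 higher and 697 lower in CCSK, where chance gives 0.294% of genes.

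Epithelial genes were lower in 18 of 19 members, with 0 higher and 1 not passed, and 18 lower when adjusted over the list alone. The list passed (list adjusted p = 9.38e-16, and adjusted p = 0.00272 with an estimated correlation). EPCAM was at least 30.1-fold lower. Podocyte genes were lower in 8 of 13 members and 5 were not passed, 8 also when adjusted over the list alone (list adjusted p = 6.58e-07), among them NPHS1, the nephrin gene (at least 7.83-fold). Of 17 distal nephron and collecting duct genes 9 were lower and 8 not passed, 9 when adjusted over the list alone (list adjusted p = 9.01e-06; adjusted p = 0.0546 with an estimated correlation), with SLC12A1, the loop of Henle cotransporter gene, at least 18.9-fold lower. Of 15 proximal tubule genes 7 were lower and 8 not passed, 8 lower when adjusted over the list alone (list adjusted p = 0.00225; adjusted p = 0.148 with an estimated correlation), and PDZK1, a scaffold gene of the brush border, was at least 8.79-fold lower. In the nephron progenitor and blastema list 8 of 17 members were lower, 2 higher and 7 not passed, 10 and 2 when adjusted over the list alone (list adjusted p = 0.000111). EYA1 was at least 10.6-fold lower and PAX2 at least 11.8-fold, while CITED1 differed by 1.95 (SE 0.33) and SIX2 by -0.96 (SE 0.44, adjusted p = 0.133). SALL1 differed by -0.84 (SE 0.28, adjusted p = 0.0363), and its adjusted p was 0.0822, 0.171 and 0.105 without fetal kidney 1, 2 and 3.

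BCOR was 5.64-fold higher than in fetal kidney (adjusted p = 2.68e-09), and 6 of 14 members of its list were higher, none lower and 8 not passed, 8 higher when adjusted over the list alone (list adjusted p = 2.10e-06). CCND1 differed by 1.73 (SE 0.65, adjusted p = 0.0600). Of 12 hedgehog pathway genes 5 were higher, 2 lower and 5 not passed, the same adjusted over the list alone (list adjusted p = 0.000400). FOXF2 was at least 15.6-fold higher, and FOXF1 and PTCH1 differed by 4.22 (SE 0.30) and 2.23 (SE 0.24). GLI1 differed by 0.63 (SE 0.31, adjusted p = 0.183). GLI2 differed by 1.25 (SE 0.35, adjusted p = 0.0109), with adjusted p = 0.143 and 0.0543 without fetal kidney 2 and 3. Of 24 neural genes 9 were higher, 2 lower and 13 not passed, 9 and 4 when adjusted over the list alone (list adjusted p = 0.00162); NEFL differed by 4.70 (SE 0.29) and NGFR was at least 8.78-fold higher, while L1CAM, a neural adhesion gene, was at least 6.26-fold lower. Of 23 PI3K and AKT genes 5 were higher, 1 lower and 17 not passed, the same adjusted over the list alone (list adjusted p = 0.0130), with IRS2 at 1.94 (SE 0.24), FOXO1 at 1.45 (SE 0.29) and AKT1 at 1.07 (SE 0.20). The neural, hedgehog and PI3K and AKT counts are on themes known from these samples, so they are not independent evidence of direction. PDGFRA differed by 1.08 (SE 0.73, adjusted p = 0.358). EGFR differed by 1.94 (SE 0.54, adjusted p = 0.00906), with adjusted p = 0.0536 without fetal kidney 2, and by -0.24 where only probe sets without a cross-hybridisation suffix were used.

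Markers of other cells differed too. Of 7 erythroid genes 5 were lower and 2 not passed, 5 when adjusted over the list alone (list adjusted p = 0.00274; adjusted p = 0.102 with an estimated correlation), with the globin gene HBB at -3.72 (SE 0.57). Of 17 endothelial genes 5 were lower, 1 higher and 11 not passed, 7 and 1 when adjusted over the list alone (list adjusted p = 0.0276; adjusted p = 0.412 with an estimated correlation). The endothelial list gave adjusted p = 0.185 and 0.0534 without fetal kidney 1 and 3. EMCN, the endomucin gene, was at least 7.87-fold lower and VWF, the von Willebrand factor gene, at least 4.91-fold higher. The other 12 lists did not pass, with members higher and lower as follows: leukocyte 1 and 0 of 21, proliferation 0 and 3 of 28, mesenchyme and matrix 0 and 5 of 25, smooth muscle and pericyte 1 and 3 of 12, skeletal muscle 0 and 1 of 10, receptor tyrosine kinases 3 and 5 of 21, neural crest and Schwann cell 2 and 5 of 10, early nephron 2 and 3 of 11, Wnt response 4 and 2 of 15, immediate early and heat shock 4 and 0 of 19, hypoxia 0 and 1 of 16, and imprinted 3 and 2 of 16. The proliferation list passed without fetal kidney 1 (adjusted p = 0.00120), and the immediate early and heat shock list without fetal kidney 2 (adjusted p = 0.0250). In all, 691 genes were higher and 1073 lower, 470 and 772 of them at least 2-fold. Centring each array on its median, which moved the median of all genes from -0.09 to 0.11, gave 1102 higher and 706 lower, and the lower count was 655 without fetal kidney 1 and 699 without fetal kidney 2. The RNA quality measure was 1.01 ± 0.707 (SD, n = 3) in fetal kidney (exact two-sided permutation test against CCSK, p = 0.262, adjusted p = 0.525; smallest p this design can give, 0.00147).

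The comparison of Wilms tumour with fetal kidney asks how the embryonal tumour differs from the tissue it resembles. Nephron progenitor genes were higher in Wilms tumour: 6 of 17 members higher, none lower and 11 not passed, 9 higher when adjusted over the list alone (list adjusted p = 5.96e-07). SIX2 was 14.72 ± 0.51 (SD, n = 15) against 12.56 ± 0.81 (SD, n = 3), 4.45-fold higher, with adjusted p = 0.00124 by limma and 0.0560 without fetal kidney 1. CITED1 was 4.66-fold higher and CRABP2, a retinoic acid binding protein gene, 4.63-fold, the latter with adjusted p = 0.0869 without fetal kidney 1. Among genes of mature nephron segments, SLC12A1 was at least 16.8-fold, NPHS1 at least 6.42-fold and PODXL, the podocalyxin gene, 15.7-fold lower. WT1 differed by 0.14 (SE 0.27, adjusted p = 0.825).

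Of 13 podocyte genes 7 were lower and 6 not passed, 10 lower and 1 higher when adjusted over the list alone (list adjusted p = 5.34e-09). Of 17 distal nephron and collecting duct genes 9 were lower and 8 not passed, 13 when adjusted over the list alone. The list passed (list adjusted p = 3.85e-11, and adjusted p = 0.00373 with an estimated correlation). GATA3, a collecting duct transcription factor gene, was at least 28.7-fold lower. Of 15 proximal tubule genes 6 were lower and 9 not passed, 9 when adjusted over the list alone (list adjusted p = 5.45e-05; adjusted p = 0.0640 with an estimated correlation). Of 19 epithelial genes 6 were lower and 13 not passed, 7 when adjusted over the list alone (list adjusted p = 3.46e-06; adjusted p = 0.0700 with an estimated correlation), with CDH16, the kidney cadherin gene, at least 5.35-fold lower. Of 11 early nephron genes 4 were lower and 7 not passed, 5 when adjusted over the list alone (list adjusted p = 0.000654; adjusted p = 0.0636 with an estimated correlation), with LHX1 at least 2.36-fold lower and JAG1, a Notch ligand gene, at -1.92 (SE 0.41). Of 21 receptor tyrosine kinase genes 7 were lower and 14 not passed, 10 lower and 1 higher when adjusted over the list alone (list adjusted p = 9.01e-06): FGFR3 was at least 12.4-fold lower and PDGFRA at least 12.3-fold lower. Of 12 hedgehog genes 2 were lower and 10 not passed, the same adjusted over the list alone (list adjusted p = 0.0115; adjusted p = 0.0828 with an estimated correlation); GLI1 was at least 6.64-fold lower and PTCH1 3.09-fold lower. The hedgehog list is a theme known from these samples, so this count is not independent evidence of direction.

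Of 25 mesenchyme and matrix genes 7 were lower and 18 not passed, 13 lower and 1 higher when adjusted over the list alone (list adjusted p = 1.70e-07; adjusted p = 0.0700 with an estimated correlation), with TWIST1 at least 3.41-fold lower and COL5A2, a fibrillar collagen gene, at -2.78 (SE 0.58). Of 17 endothelial genes 9 were lower and 8 not passed, 9 lower and 1 higher when adjusted over the list alone. The list passed (list adjusted p = 6.58e-07), but only narrowly with an estimated correlation (adjusted p = 0.0471). EMCN was at least 8.25-fold lower. Of 10 neural crest and Schwann cell genes 5 were lower and 5 not passed, 7 when adjusted over the list alone (list adjusted p = 5.43e-06), with TFAP2B, which encodes a transcription factor active in kidney too, at least 2.41-fold lower. Of 7 erythroid genes 4 were lower and 3 not passed, 5 when adjusted over the list alone (list adjusted p = 0.000396; adjusted p = 0.0640 with an estimated correlation). HBB differed by -2.61 (SE 0.57, adjusted p = 0.00330), with adjusted p = 0.107 without fetal kidney 1. The proliferation list passed as higher although 0 of its 28 members did (list adjusted p = 0.000320; adjusted p = 0.498 with an estimated correlation, and 0.0541 without fetal kidney 1). Among single genes, IGF2-AS, annotated as antisense to IGF2 and named here from the probe annotation alone, was at least 4.48-fold higher, although signal from IGF2 itself was not told apart from it. PRAME, a cancer-testis antigen gene, was at least 12.5-fold higher, with adjusted p = 0.0685 and 0.0533 without fetal kidney 2 and 3. AFP, the alpha-fetoprotein gene, was 7.55 ± 0.75 (SD, n = 15), at or below the background level in 15 of 15 Wilms tumours, against 12.63 ± 0.87 (SD, n = 3), and SULT1E1, an oestrogen sulfotransferase gene, was at least 22.4-fold lower. Genes always named did not pass for NGFR (1.79, SE 0.66), CCND1 (-1.90, SE 0.64), BCOR (0.37, SE 0.25), EGFR (-1.40, SE 0.53), GLI2 (-0.56, SE 0.35), TCF21 (-1.58, SE 0.71), PAX2 (0.58, SE 0.84), PAX8 (-0.19, SE 0.41) and SALL1 (0.82, SE 0.28).

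The other 10 lists did not pass in Wilms tumour against fetal kidney, with members higher and lower as follows: neural 3 and 2 of 24, PI3K and AKT 1 and 1 of 23, BCOR and YWHAE sarcoma 1 and 0 of 14, Wnt response 1 and 3 of 15, skeletal muscle 1 and 0 of 10, smooth muscle and pericyte 0 and 2 of 12, leukocyte 1 and 0 of 21, immediate early and heat shock 0 and 2 of 19, hypoxia 1 and 2 of 16, and imprinted 0 and 2 of 16. In all, 261 genes were higher and 459 lower, 120 and 397 of them at least 2-fold. With the arrays centred on their medians, which moved the median of all genes from -0.01 to 0.20, 750 genes were higher, 68.8% of all calls against 36.2% otherwise. Without fetal kidney 1 the counts were 45 higher and 163 lower, 39 and 161 of them at least 2-fold. Without fetal kidney 2 they were 127 higher and 238 lower, with 227 at least 2-fold lower. The RNA quality measure did not pass between these groups (exact two-sided permutation test, p = 0.412, adjusted p = 0.525; smallest p this design can give, 0.00123).

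**Figure D3:**
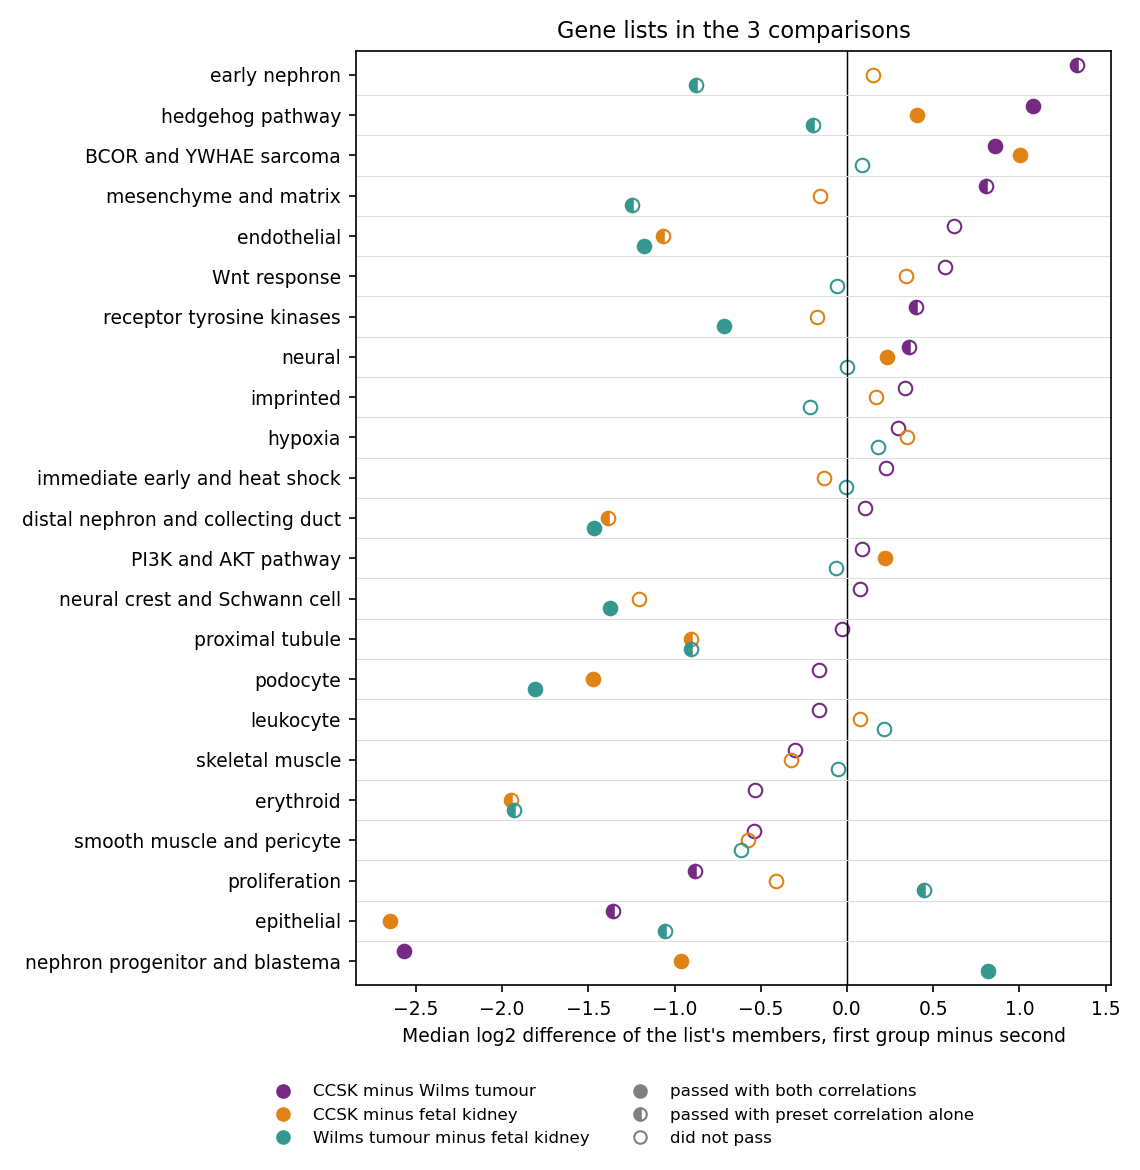
Median log2 difference of the measured members of each of 23 gene lists in the 3 comparisons; filled points passed with both the preset and an estimated correlation, part-filled points with the preset correlation alone, and open points did not pass. The nephron progenitor list lies at -2.57 for CCSK minus Wilms tumour and at 0.82 for Wilms tumour minus fetal kidney.

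Genes at least 2-fold higher in CCSK than in both other groups numbered 364, and 414 were at least 2-fold lower than in both. Lists of these sizes drawn independently would share 39.6 and 62.9. The comparisons share the CCSK samples, so each was also run on separate sets of 7 CCSK samples over 20 splits, which gave medians of 329 (312 to 351) and 369 (342 to 392). Of the 844 genes at least 2-fold higher in CCSK than in Wilms tumour, 399 were also higher in CCSK than in fetal kidney and 200 were lower in Wilms tumour than in fetal kidney, 38 of them both, and 283 neither. This division rests on 3 fetal kidneys. Without fetal kidney 1, 2 and 3, of 841, 840 and 840 such genes, the 399 became 337, 329 and 316, the 200 became 88, 107 and 153, and the 283 became 431, 425 and 392. FOXF1 and BCOR were higher in CCSK than in both other groups. GLI1 and PDGFRA were lower in Wilms tumour than in fetal kidney, with no passed difference between CCSK and fetal kidney. Of the 817 genes at least 2-fold lower in CCSK than in Wilms tumour, 464 were also lower than in fetal kidney, 66 were higher in Wilms tumour than in fetal kidney, 9 were both and 296 neither. Without fetal kidney 1, 2 and 3, of 817, 815 and 817 such genes, these were 347, 337 and 345, then 16, 38 and 49, then 0, 2 and 4, and last 454, 442 and 427.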

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

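The count in this part was not among the planned tests and was made after the data were seen. Of 2144 kept probe sets that had no single gene symbol, and so stood outside the gene comparisons, 299 passed the threshold with at least a 2-fold difference in CCSK against Wilms tumour, 176 higher and 123 lower. In CCSK against fetal kidney 186 of them did so, 69 higher and 117 lower, and in Wilms tumour against fetal kidney 105, 17 higher and 88 lower. No sample was examined for lying far from its group, since the groups held 3, 14 and 15 samples, outside the range of group sizes for that rule.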

How the results depend on the processing

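The largest pseudocount and the fit without Wilms tumours 1 to 3 were chosen after seeing the data, and the other alternatives were planned. Signal over background limits the genes of the dimmer group, whose fold is then a lower bound, and the 3 fetal kidneys limit both comparisons made with them. Over 19 alternatives other than leaving out single samples, 5260 of 5520 values of named genes stayed, 232 lost the call, 23 gained it and 5 turned. A value that stayed kept its side of the threshold, and its direction if it had passed. For genes and lists alike, a turn was not counted where neither fit passed. The replicate block alone accounts for 72 of the lost calls. Over the 32 fits that left out a single tumour or kidney, 9163 of 9504 stayed, 327 lost the call, 14 gained it and 0 turned. In many of these the sample left out was in neither group of the comparison. The difference cannot change there, only the estimate of the spread and the adjusted p. Most named genes were also chosen because they passed. These shares were thus in part fixed in advance and overstate the stability. Of the calls, 71, 54 and 40 were lost without fetal kidney 1, 2 and 3. Apart from the replicate block, no alternative or left-out sample changed 90 of 104 named genes in CCSK against Wilms tumour, 63 of 102 in CCSK against fetal kidney and 37 of 91 in Wilms tumour against fetal kidney. A gene not measured under an alternative counted as unchanged there. Only 195 of 297 values existed where only probe sets without a cross-hybridisation suffix were used, and 276 with the stricter filter. In CCSK against Wilms tumour 28 called genes had another probe set called in the opposite direction.

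Where only probe sets without a cross-hybridisation suffix were used, fewer genes were tested. CCSK against Wilms tumour then gave 1188 higher and 1637 lower, 531 of them at least 2-fold lower. CCSK against fetal kidney gave 455 higher and 663 lower, 490 at least 2-fold lower. Wilms tumour against fetal kidney gave 136 higher, 67 at least 2-fold, and 262 genes were at least 2-fold lower in CCSK than in both. Under that choice the difference turned for APC (0.61) and EGFR (-0.22) in CCSK against Wilms tumour, and for TSC2 (0.016), EGFR (-0.24) and PHLDA2 (-0.074) in CCSK against fetal kidney. None of these 5 passed, and the cause was not tested. Quantile normalization gave 197 genes at least 2-fold higher in Wilms tumour than in fetal kidney, and the cause was not tested. Median centring gave 1102 higher and 706 lower for CCSK against fetal kidney and 750 higher, 287 of them at least 2-fold, for Wilms tumour against fetal kidney, whose median over all genes it moved from -0.01 to 0.20. The replicate numbers did not pair the samples, since the residuals of the 12 CCSK and Wilms tumours that share a number correlated at -0.21 to 0.03. With these numbers as a replicate block, which leaves fewer degrees of freedom, CCSK against fetal kidney gave 434 higher and 673 lower, and Wilms tumour against fetal kidney 46 and 205, 39 and 203 of them at least 2-fold. Leaving out each sample in turn gave 655 to 1094 lower in CCSK against fetal kidney. In Wilms tumour against fetal kidney it gave 45 to 286 higher, 163 to 515 lower, 39 to 159 at least 2-fold higher and 161 to 438 at least 2-fold lower, each lowest value being that without fetal kidney 1, which leaves 2 kidneys.

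With an estimated correlation 3, 7 and 6 lists passed in the 3 comparisons, where 9, 11 and 13 did with the preset one. Only the correlation between genes differed between these tests. For the lists that lost the call its estimates ran from 0.0352 (neural) to 0.598 (proliferation), above the preset 0.01. Over 4 alternatives 253 of 276 list tests stayed, 19 lost the call and 4 gained it. Quantile normalization added the PI3K and AKT list in CCSK against Wilms tumour (adjusted p = 0.0374), the proliferation list in CCSK against fetal kidney (0.0210) and the leukocyte list in Wilms tumour against fetal kidney (0.0296). With the replicate block the endothelial list passed in CCSK against Wilms tumour (0.0349) and did not in CCSK against fetal kidney (0.120), nor did the hedgehog list in Wilms tumour against fetal kidney (0.188). Without each fetal kidney 202 of 207 list tests stayed. Those of CCSK against Wilms tumour among them, whose groups hold no fetal kidney, could change little.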

Other observations

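In this part the homeobox symbols were chosen after LHX2, MNX1 and EN2 had been seen among the largest differences, and further PAX genes were added after a first count. The widened list of neuronal transcripts, the sets matched on SD, the matched sets for the proliferation list and the tests of dilution on marker medians and on endothelium alone were also set after first values were seen. So were the homeobox count without the prompting genes and the relations of the Wilms tumour genes with leukocyte and endothelial markers, which the test of mesenchymal cells takes in. Homeobox genes, which encode transcription factors that set position and cell identity in the embryo, were frequent among the genes at least 2-fold higher in CCSK than in both other groups. They made up 20 of these 364 genes, of 92 homeobox genes tested, and those named here were picked after their values were seen. The 2-fold limit of this count did not use the background level, and some of the 20 were dim. Against that level POU3F3 was at least 1.01-fold over Wilms tumour and 0.88-fold over fetal kidney, with 5 of 14 CCSK at or below it. POU3F2 was at least 1.30-fold and 1.13-fold, and MSX2 at least 1.67-fold over fetal kidney. NKX3-2, a gene of skeletal mesoderm, was at least 9.09-fold higher than in Wilms tumour and at least 8.55-fold higher than in fetal kidney, and PAX6, a gene of eye and neural tube, at least 8.97-fold and 7.82-fold. PITX1, a gene of hindlimb identity, was 10.52 ± 0.39 (SD, n = 14) in CCSK, 6.78 ± 0.73 (SD, n = 15) in Wilms tumour and 6.31 ± 0.29 (SD, n = 3) in fetal kidney. Against Wilms tumour and fetal kidney IRX5 was at least 6.23-fold and 4.22-fold higher, and HOXC13 at least 3.38-fold and 3.18-fold. At the other end of the set HOXC6 differed by 1.01 (SE 0.17) and 1.21 (SE 0.29). The difference of MSX2 from fetal kidney had adjusted p = 0.0388, and 0.433 and 0.0601 without fetal kidney 1 and 3. That of VAX2 had adjusted p = 0.00432, and 0.0503 and 0.0481 without fetal kidney 2 and 3. The set held 19 of the 20 genes after quantile normalization, 19 after median centring, and 12 where only probe sets without a cross-hybridisation suffix were used, which tested 62 homeobox genes. Of the 414 genes at least 2-fold lower in CCSK than in both, 5 were homeobox genes (MEOX1, PAX2, MEIS1, PAX8 and HOXD1), against a mean of 2.97 in matched random sets (one-sided p = 0.18). HOXD1 had adjusted p = 0.0361 against fetal kidney, and 0.0653, 0.148 and 0.145 without fetal kidney 1, 2 and 3.

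Random sets of 364 genes matched on the mean level in Wilms tumour and fetal kidney held 5.35 homeobox genes on average and at most 10 in the central 95% of draws, against 20 observed. Because the class was picked from these data, LHX2, MNX1, EN2 and all PAX genes were then left out. Of the other 84 homeobox genes 16 were among 360 genes, against 4.48 on average and at most 9 in the central 95% of matched sets. Compared with these sets the one-sided p was 0.0001, the smallest that 10000 draws can give. The draws take genes as independent, whereas homeobox genes may vary together across the same 14 CCSK, so this p is no error rate. A gene dim in both other groups could pass the filter only through CCSK, which holds for the matched genes too. The higher count than in equally dim genes argues against a low level in kidney, leaving room only to be higher, as the whole cause. It does so without an error rate. An admixture of mature neurons stays open, since the 52 measured genes of a widened list of 65 neuronal transcripts, 24 of them in the neural list, went both ways: 18 higher, 9 lower and 25 not passed against Wilms tumour (median 0.24), and 16, 3 and 33 against fetal kidney (median 0.098), and a first list of 30, which had left out genes already seen to be high, gave 6 higher, 4 lower and 11 not passed against Wilms tumour. Of the 52 genes, 14 had a difference from Wilms tumour above 1 and 6 had one below -1. Against Wilms tumour NEFL, NPTX1, GAD1, NRCAM, MAPT, OLFM1 and SNCB were at least 49.9-fold, 38.5-fold, 21.8-fold, 9.38-fold, 5.68-fold, 4.10-fold and 3.05-fold higher. INA, NPTX2, KIF5C and CRMP1 differed by 3.54, 3.42, 1.54 and 1.51. The 6 were ENO2, at least 3.07-fold lower, and NES, SV2A, CNTNAP2, ELAVL4 and PCLO, at -2.46, -1.89, -1.76, -1.58 and -1.06. These last differences are no bounds, since each gene had CCSK samples at or below the background level. SNAP25 and GAP43 differed by -0.15 and -0.01 at CCSK levels of 10.37 and 10.18, and SYT1, SYP, SYN1, SYN2 and STX1A did not pass. A homeobox programme of the CCSK cells themselves may account for the set too, as a hypothesis found and tested on the same samples, and a different tissue of origin and other admixed cells were not tested.

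The proliferation genes were lower in CCSK than in Wilms tumour in 25 of 28 members, with a median of -0.88, and 25 were lower with the 3 prime over 5 prime ratio as a covariate, which moved the difference of a gene by a median of only 0.017, so that RNA quality stays open. Quantile normalization moved it by 0.027 and tests nothing here either, but random sets of other genes matched on mean level had a median of -0.12 (central 95% of 10000 sets -0.33 to 0.11), which argues against scaling as the whole cause. Dilution by leukocytes and endothelium together would raise the markers of both. The log2 rises need not be equal, since each depends on how much of that cell type was already present. Their median differences were -0.16 (bootstrap 95% interval over samples -0.50 to 0.27) and 0.62 (0.21 to 1.06). These were apart by 0.79 (0.31 to 1.17), or by 0.46 (0.09 to 0.70) with values raised to the background level. The 2 marker sets thus did not move by the same amount, which does not decide on dilution by both. Dilution by 1 cell type or by other cells stays open too. A relation with mesenchyme and matrix genes, of which 15 of 25 were higher in CCSK and 4 lower, was not tested. Across samples the proliferation list fell with leukocyte and endothelial markers together in 14 CCSK (r = -0.621, permutation p = 0.0196, adjusted p = 0.0457 over 7 relations). The rank correlation did not pass when adjusted (rho = -0.640, permutation p = 0.0158, adjusted p = 0.0553), and r was -0.498 without the 2 samples farthest from the median. In 15 Wilms tumours r was -0.154 (p = 0.582, adjusted p = 0.815) and rho was -0.100 (p = 0.724), with r = -0.169 without 2 samples. With endothelial markers alone r was 0.0051 in CCSK (p = 0.987; rho = 0.029, p = 0.929; r = -0.019 without 2) and 0.018 in Wilms tumours (p = 0.951; rho = 0.018, p = 0.954; r = -0.033 without 2; adjusted p = 0.987 for both), with intervals too wide to decide, so that endothelium stays open, and a lower share of cycling cells in CCSK may account for the difference but was not tested.

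The other pattern is that 162 genes at least 2-fold higher in CCSK than in Wilms tumour were lower in Wilms tumour than in fetal kidney, with no passed rise of CCSK over fetal kidney; 69, 82 and 121 of them were still called lower without fetal kidney 1, 2 and 3. Of the 162, 140 (86.4%) were still called lower in Wilms tumour after quantile normalization and 132 after median centring. These corrections moved the median of all genes only from -0.01 to 0.09 and to 0.20. Most of the calls thus outlast these 2 corrections, but shifts this small cannot decide on scaling, which stays open. Across 15 Wilms tumours the mean of 155 of them, 7 members of the mesenchyme and matrix list being left out, rose with the mean of that list (r = 0.753, permutation p = 0.00111, adjusted p = 0.00777; rho = 0.754, p = 0.0017; r = 0.626 without 2 samples), and of 1000 random gene sets matched on mean level 100% had a lower r (median 0.350, 95th percentile 0.534), and of those matched on SD 97.3% (median 0.563, 95th percentile 0.728). The relation may not be particular to mesenchyme. With 3 leukocyte or endothelial members also left out, 152 of the genes rose with leukocyte and endothelial markers together (r = 0.675, permutation p = 0.00593, adjusted p = 0.0208). The rank correlation did not pass when adjusted (rho = 0.568, permutation p = 0.0305, adjusted p = 0.0713), and r was 0.567 without 2 samples. With endothelial markers alone neither correlation passed when adjusted (r = 0.547, p = 0.0352, adjusted p = 0.0616, and rho = 0.518, p = 0.0511, adjusted p = 0.0894). There r was 0.352 without 2 samples. Whether these 2 relations differ was not tested. The endothelial list was lower in Wilms tumour than in fetal kidney too, in 9 of 17 members, so that mesenchymal cells cannot be told apart from other admixed cells, and a difference in the tumour cells themselves stays open and untested.

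In CCSK against Wilms tumour 1 of 100 splits of the samples into groups of the same sizes, the real one included, gave as many genes past the threshold as the real 4488, and the highest of the others gave 2445. In CCSK against fetal kidney 1 of 100 splits did, with 1764 genes against at most 251 in the others, and in Wilms tumour against fetal kidney 1 of 100, with 720 against at most 13. No other split reached these 3 counts, and 1 of 100 is the smallest share that this number of splits can give. The splits do not test the size of a count, and the counts against fetal kidney fell when fetal kidney 1 was left out.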
